A study of Mus musculus with 6 samples.

How the data were processed

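RNA sequencing was performed on CD4 T cells of C57BL/6 mice aged 7 weeks, either wild-type (WT) or lacking NLRP3 (NLRP3KO), the sensor protein of an inflammasome. Each genotype gave 1 library of naive cells, 1 library of cells cultured under T helper type 2 (Th2) conditions for 3 days and 1 library of cells cultured for 6 days, 6 libraries in all. Per the labels' protocols, Th2 cells were made with IL-4 at 10 ng/ml and an antibody blocking interferon gamma on plates coated with CD3 and CD28 antibodies. Per the labels, RNA came from 300000 cells, 1 µg of total RNA was depleted of ribosomal RNA for the 4 Th2 libraries, and the 2 naive libraries were made from purified mRNA. Libraries were amplified for 12 PCR cycles to fragments of about 300 bp and sequenced on a MiSeq instrument, per the labels' protocols.

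The authors deposited 1 gene table per library, with the FPKM (fragments normalized to transcript length and to mapped fragments), its lower and upper confidence bound and a status for each gene model, per the file headers. TopHat, Cufflinks and the mm9 genome build are named in the submitters' processing notes. Their versions and the gene annotation are not given in the sources used here. Each table held 23700 entries, of which 285 carried a status of too little data and were left out, which left 23415 entries with 23091 symbols. Coordinates are those of the deposited tables on mm9, counted from 1. The reference available here was another build (GRCm38) and served only for transcript lengths, GC content and exon numbers, matched by symbol, and for older symbols of 4 listed genes.

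The deposited values are not counts, so no count test was used. FPKM were scaled between libraries by the median ratio to the geometric mean over the 1059 genes with an FPKM of at least 1 in all 6 libraries. The factors were 0.328 for naive WT, 0.245 for naive NLRP3KO, 2.02 for WT day 3, 1.78 for NLRP3KO day 3, 1.83 for WT day 6 and 1.62 for NLRP3KO day 6. Each difference between 2 libraries is the log2 of scaled FPKM plus a pseudocount of 1, which understates the difference of genes with low values. Genes with an FPKM of at least 1 in at least 1 of the 2 libraries were kept, and those at least 2-fold apart on this scale were counted. FPKM printed in the text are as deposited, and log2 differences are after scaling. With 1 library per group there were no replicates, so no comparison has a replicate check and no p-value is given.

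Sequencing depth was read from the confidence bounds. In the Th2 libraries between 87.3% and 93.1% of genes with a lower bound above 0 had bounds in a ratio of whole numbers up to 80, within a relative tolerance of 2e-05. In naive WT and naive NLRP3KO the shares were 52.5% and 55.0%. Taking 1 fragment to give an upper bound of 3 steps, gene models with a single exon and a span of at least 1000 bases gave the total to which each library had been normalized. These totals were 4571257 fragments for naive WT, 3112345 for naive NLRP3KO, 604216 for WT day 3, 475361 for NLRP3KO day 3, 562337 for WT day 6 and 129744 for NLRP3KO day 6. Fragment numbers per gene were then estimated from FPKM and bounds, and fragments on genes are their sum without small RNAs, Rn45s and gene models of up to 300 bases. They are inferences, and none could be recovered for Il4, Il5, Il13, Eif2s3y, Kdm5d and Uty. Intervals and floors built on them cover counting error only, since the libraries were amplified by PCR without molecular identifiers. Intervals compare the fragments of 2 libraries, not the conditions.

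A value of exactly 0 can be a failed estimate in such tables, so these genes are described as listed at 0, with each library's value and no fold. Between 314 and 678 of the zeros per library carried an upper bound above 0, while the others had bounds of 0 and 0. The deposited FPKM lay outside its own bounds for 272 genes in naive WT, 183 in naive NLRP3KO and between 9 and 20 in each Th2 library. Dapl1, H2-Q6 and Cd3e were among these in the naive libraries. Genes that share reads with near-identical copies (alpha and beta globins, histones, H2-Q genes, ribosomal proteins with pseudogenes) have uncertain values.

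The comparisons, the gene lists, the rule for named genes and the first alternatives were fixed before the data were examined. The rule named Nlrp3, Il4, Il5, Il13, Gata3, Irf4 and Maf in every library. It then took the 12 highest and 12 lowest genes of each genotype comparison and the 10 highest and 10 lowest of each other comparison. This ranking ran over genes with an FPKM of at least 5 in 1 library and with bounds that did not overlap. Small RNAs, immunoglobulin and T cell receptor segments and unnamed models were left out of it, as were histone genes in comparisons with naive cells. The rule also took up to 4 members of each list that were at least 2-fold apart. Since many of the top genes were listed at 0 in 1 library, the same ranking among genes above 0 in both libraries was added after seeing the data. A few genes that the rule took are not reported here.

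There were 16 lists of gene groups, 8 lists of cell type markers and 3 lists of sex-linked and quality-related RNAs. Of the last 3, the list of mitochondrially encoded genes had no member in the tables, and 2 of the 10 non-polyadenylated RNAs were not matched. For each list the median log2 difference of kept members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Where members were listed at 0 in 1 library, the median was also taken with zeros placed at the value of 3 fragments, leaving out members whose other value lay at or below that floor. The percentile describes these libraries and is not a test of the condition. Members' fragments were also pooled as a share of all fragments on genes, with an exact binomial (Clopper-Pearson) interval of 95%, an alternative added after seeing the data. Pooling took all matched members with fragment numbers, also those that the minimum FPKM left out of the median. Leaving out each member in turn was added as well. Bootstrap intervals, given for list medians between the naive libraries, resampled the list members. They describe the spread among genes of these 2 libraries, and genes are not replicates of a genotype.

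Alternatives fixed in advance were a pseudocount of 0.1, a minimum FPKM of 5, no minimum, FPKM as deposited, upper-quartile scaling and a count restricted to genes whose bounds did not overlap. Added after seeing the data were the same restriction to genes above 0 in both libraries, scaling over 5 libraries without NLRP3KO day 6, and scaling by the total of fragments on genes. To show what counting error alone gives, the fragments of each gene were split at random between the 2 libraries of a comparison 100 times, over 11949 genes. The counting rules were tested on simulated fragments with 200 changed genes. Among the naive libraries the rule on bounds recovered 97% of 4-fold changes with 0 false calls. At day 3 it recovered 34% of 4-fold changes with 15 false calls and 55% of 8-fold changes with 14 false calls. At day 6 it recovered 9.5% of 4-fold changes with 8 false calls and 22.5% of 8-fold changes with 7 false calls. In the runs with 4-fold changes, the 2-fold rule without bounds passed 1 unchanged gene between the naive libraries, 2057 at day 3 and 2760 at day 6. Counts of genes at least 2-fold apart in the Th2 libraries, list members included, can therefore hold many that differ by counting error alone. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.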

Results

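The role of NLRP3 in Th2 cells was addressed by sequencing RNA of naive CD4 T cells and of cells kept for 3 or 6 days under Th2 conditions, from WT and NLRP3KO mice. Each of the 6 groups was a single library, so differences are between libraries. The libraries differed widely in depth. The 2 naive libraries held an estimated 1270988 (WT) and 1107277 (NLRP3KO) fragments on genes, while the Th2 libraries held 23436 (WT day 3), 20175 (NLRP3KO day 3), 24536 (WT day 6) and 4358 (NLRP3KO day 6). The precursor of ribosomal RNA, Rn45s, had FPKM of 10783 and 7819 in naive WT and NLRP3KO, 57645 and 63242 at day 3, and 53218 and 67266 at day 6. Its share of fragments is not given, since its FPKM and its bounds led to unlike fragment numbers. Genes above 0 numbered 12875 and 12570 in the naive libraries, 6746 and 6369 at day 3, and 6881 and 2777 at day 6. On a transcript of 2 kb, 3 fragments corresponded to an FPKM of 0.328 in naive WT, 0.482 in naive NLRP3KO, 2.48 in WT day 3, 3.16 in NLRP3KO day 3, 2.67 in WT day 6 and 11.6 in NLRP3KO day 6. Where a value rested on fewer fragments than that, as many of the lower values below did, the size of the difference is uncertain.

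Nlrp3 itself (chromosome 11, 59356188 to 59380458 on mm9) had an FPKM of 0.0569 in naive WT and was listed at 0 in the other 5 libraries. The FPKM that 3 fragments on Nlrp3 would give was 0.171 in naive WT, 0.251 in naive NLRP3KO, 1.29 in WT day 3, 1.64 in NLRP3KO day 3, 1.39 in WT day 6 and 6.01 in NLRP3KO day 6. The WT value thus lay below that floor, and the loss of Nlrp3 could not be checked at this depth. Of the type 2 cytokines, Il4 had an FPKM of 3.77 (bounds 0 to 18.9) in WT day 3 and was listed at 0 elsewhere. Il5 was above 0 in naive NLRP3KO alone, at 0.237, and Il13 was listed at 0 in all 6 libraries. Gata3, the transcription factor that directs Th2 differentiation, had FPKM of 13.5 and 16.2 in naive WT and NLRP3KO, 15.6 and 14.4 at day 3, and 11.0 and 5.03 at day 6. Irf4, a transcription factor induced by antigen receptor signalling, stood at 2.33 and 4.57 in naive WT and NLRP3KO, 21.9 and 20.4 at day 3, and 20.4 and 15.3 at day 6. Maf, which activates the Il4 promoter, was 4.73 and 4.83 in the naive libraries, 0 and 1.80 at day 3, and 0 and 4.41 at day 6.

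At day 3, the genes furthest above WT in the NLRP3KO library, among those detected in both, included Tgm2, Id2, Srgn and Ecm1. Tgm2, a transglutaminase, had an FPKM of 17.3 (bounds 11.3 to 23.1) against 0.486 (0 to 1.40), a log2 difference of 4.0. Id2, an inhibitor of basic helix-loop-helix transcription factors, was 24.3 against 1.47 (log2 difference 3.48), and Srgn, the proteoglycan of secretory granules, was 58.4 against 6.27 (2.94). Ecm1, a secreted matrix protein made by Th2 cells, was 58.8 (42.0 to 75.6) against 6.62 (0.946 to 12.3), a log2 difference of 2.88. Egln3, a prolyl hydroxylase acting on hypoxia-inducible factors, was 20 against 2.0 (2.88). Ndrg1 was 13.0 against 1.21 (2.82), Bnip3, a mitophagy receptor, 14.4 against 2.06 (2.37), the glucose transporter gene Slc2a3 35.3 against 5.64 (2.37), and the endoplasmic reticulum oxidase gene Ero1l 25.1 against 3.49 (2.51). Spop, Serpinf1 and Vdac1 completed the 12 highest genes. Il24, a cytokine of the IL-10 family that Th2 cells make, had an FPKM of 19.5 (7.54 to 30.2) in NLRP3KO and was listed at 0 in WT. Penk, the precursor of enkephalins, was likewise 11.6 against 0, S100a6, a calcium-binding protein gene, 22 against 0, and Ier3 8.91 against 0.

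Genes lower in the NLRP3KO day 3 library included Shmt2, Slc7a5, Ranbp1 and Lmnb1. Shmt2, the mitochondrial serine hydroxymethyltransferase, had an FPKM of 1.95 (0 to 4.89) against 16.9 (9.20 to 24.5), a log2 difference of -2.97. Mthfd2, which acts in the same mitochondrial folate pathway, was listed at 0 in NLRP3KO and was 9.46 in WT. Slc7a5, a transporter of large neutral amino acids, was 0.625 against 6.88 (-2.82), and Hspa9, the mitochondrial Hsp70 chaperone, 2.18 against 13.7 (-2.56). Ranbp1, a regulator of nuclear transport, was 2.98 against 21.1 (-2.79), Lmnb1, which encodes lamin B1, 0.780 against 7.36 (-2.73), and Hmgb1 0.567 against 6.12 (-2.73). The splicing factor gene Srsf2 was 2.39 against 12.2 (-2.29), and Nxf1, an mRNA export factor, 0.984 against 6.97 (-2.45). Histone genes, which share reads, were also among them, with Hist1h3c at 3.14 against 61.5 (-4.25).

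**Figure D1:**
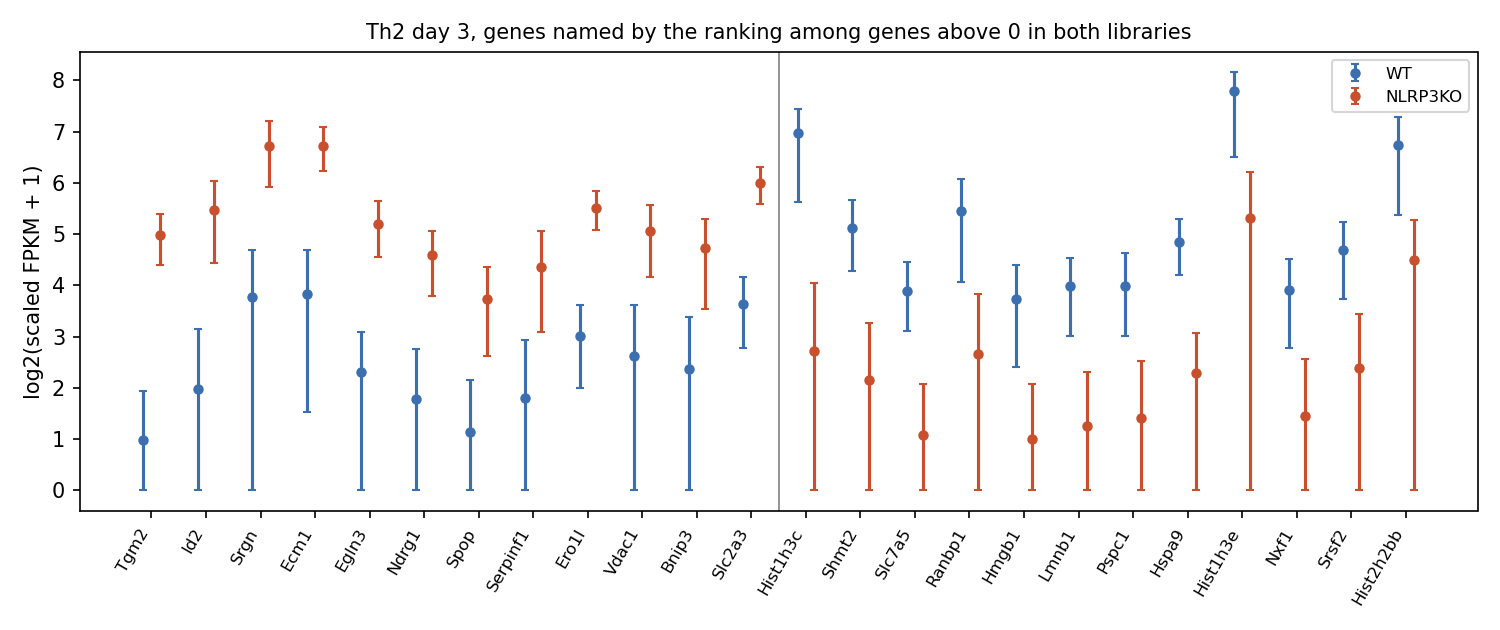
FPKM with deposited 95% bounds in the WT and NLRP3KO day 3 libraries for genes named in the text. Ecm1 stands at 58.8 in NLRP3KO and 6.62 in WT, and Shmt2 at 1.95 and 16.9.

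Several fixed lists stood apart at day 3. Of 8 regulatory T cell (Treg) list genes kept, 5 were at least 2-fold higher in NLRP3KO and 0 lower. Their median log2 difference of 1.23 lay at percentile 99.8 of matched random lists (0.90 with the member listed at 0 placed at its floor of 3 fragments). Pooled over 10 list members, kept or not, fragments were 1.83 times those of WT as a share of gene fragments (95% interval 1.37 to 2.44). Among the kept genes were Tnfrsf18, the GITR receptor gene, at 29.3 against 3.85, Ctla4, an inhibitory receptor gene, at 10.6 against 1.85, and Lrrc32 at 3.44 against 0.902. Foxp3, which defines Treg cells, was listed at 0 in both day 3 libraries. Proliferation genes lay the other way. Of 19 kept, 8 were at least 2-fold lower and 1 higher, with a median of -0.87 (percentile 0.16) and a pooled ratio of 0.589 (0.460 to 0.752). The mitotic genes Ccnb2 and Aurka were 1.51 against 5.93 and 1.20 against 4.70, and Mcm5, part of the replicative helicase, was 1.93 against 5.56. Among p53 and apoptosis genes 5 of 9 were higher and 1 lower (median 1.01, percentile 97.7, 0.75 with zeros at their floor, pooled ratio 1.87, 1.28 to 2.76), with Phlda3 at 11.1 against 2.51. All these medians kept their sign under each scaling.

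Among glycolysis genes at day 3, Pgk1 was 36.8 against 12.0 and Pgam1 34.9 against 13.7, 2 of 13 were at least 2-fold higher and 0 lower, and the median was 0.30 (percentile 85.5). Their pooled ratio was 1.23 (1.06 to 1.43), and 1.13 (0.961 to 1.34) without Aldoa. Cholesterol synthesis genes had 5 of 13 higher and 0 lower (median 0.66, percentile 96.6, 0.15 with zeros at their floor), with Hmgcs1 at 5.36 against 1.32 and Sqle at 4.85 against 1.27. Their pooled ratio of 1.5 (1.03 to 2.21) became 1.35 (0.906 to 2.02) without Hmgcs1. Stress response genes had 6 of 12 lower and 2 higher (median -0.95, percentile 1.62), but 4 members were listed at 0 in 1 library and the pooled ratio was 0.661 (0.418 to 1.03). With zeros at their floor the median was 0.12, and with a minimum FPKM of 5 it was -0.05. The Th2 list had 6 of 14 higher and 2 lower, a median of -0.03 (percentile 47.2) that turned positive as deposited and under 2 of the other scalings, and a pooled ratio of 1.40 (1.11 to 1.76) that was 1.04 (0.808 to 1.34) without Ecm1. Of 5 inflammasome genes, 3 were higher and 1 lower (median 1.97, percentile 98.5, but -0.34 with zeros at their floor), with a pooled ratio of 2.11 (0.965 to 4.88) on 20 and 11 fragments. Txnip, which binds thioredoxin, was 12.7 against 2.5, and Pycard, the inflammasome adaptor gene, 4.23 against 0. T cell markers had a median of 0.02 (percentile 53.8, 0.34 with zeros at their floor) and a pooled ratio of 1.39 (0.898 to 2.16), and ribosomal protein genes had 0.05 (percentile 59.1) and 0.967 (0.817 to 1.14). The list of non-polyadenylated RNAs, which holds histone genes and Rn45s, had a median of -0.70 (percentile 3.83).

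Over all 5749 genes kept at day 3, 1461 were at least 2-fold higher and 1563 lower in NLRP3KO, and 34.4% were listed at 0 in 1 library. Random splits of the same fragments gave on average 1349 higher (at most 1425) and 1286 lower (at most 1381), where the observed fragments gave 1352 and 1480. The higher count thus lay within the range of counting error and the lower count above it. Requiring a value above 0 in both libraries and bounds apart left 47 genes higher and 32 lower by at least 2-fold. On estimated fragments, with Poisson bounds and without the 2-fold requirement, 79 genes lay apart, against 11.8 on average in the splits (5 to 20).

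At day 6 the NLRP3KO library again held more Ecm1, at 57.3 (26.4 to 92.5) against 8.09 (1.01 to 15.2), a log2 difference of 2.57. Lrrc32, which presents latent TGF-beta on Treg cells, was 8.40 against 0.484 (2.96), Igfbp4, an insulin-like growth factor binding protein gene of naive T cells, 44.2 against 7.39 (2.33), and the lymphocyte GTPase gene Gimap6 31.6 against 3.63 (2.78). Malat1, a nuclear noncoding RNA, was 114 against 47.0 (1.10), and Scd2, a fatty acid desaturase gene, 50.9 against 21.4 (1.06). S100a13 and S100a6 were 67.9 and 54.0 in NLRP3KO and listed at 0 in WT, and Il24 was 15.9 (0 to 34.5) against 0. Lower in NLRP3KO were Hsp90ab1, a cytosolic chaperone gene, at 18.0 (3.07 to 30.7) against 99.4 (80.9 to 118) and a log2 difference of -2.60. Atf4, a transcription factor of the amino acid response, was 4.89 against 29.2, Cct2, a chaperonin subunit gene, 4.25 against 28.8, Hnrnpu 2.19 against 18.1, and Hspa9 2.66 against 15.9. These 4 had bounds apart, but their NLRP3KO values rested on an estimated 0.6 to 0.7 fragments, so no size is given. Myc, Mcm7 and Ccna2 were listed at 0 in NLRP3KO and at 10.2, 9.46 and 8.66 in WT, but 3 fragments in NLRP3KO day 6 corresponded to 12.2, 12.3 and 9.14, so their difference could not be measured.

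Of 20 proliferation genes at day 6, 13 were at least 2-fold lower and 3 higher, 11 of them listed at 0 in 1 library. The median was -1.61 (percentile 1.30), or -0.21 over the 13 members that could be placed with zeros at their floor, and the pooled ratio was 0.606 (0.380 to 0.925). Over all 5336 genes kept, 2869 were at least 2-fold lower and 1113 higher, so a count of lower members alone says little here. Cholesterol synthesis genes lay higher, 6 of 10 at least 2-fold and 0 lower (median 1.30, percentile 99.0, 0.82 with zeros at their floor). Pooled over 14 entries of this list, kept or not, the ratio was 3.58 (1.97 to 6.38), from 21 and 33 fragments. For other lists the median and the pooled ratio pointed apart. Part of this lay in scaling, as pooled ratios are shares of fragments on genes. With that scaling the median of genes above 0 in both libraries moved from 0.33 to 0.83. On the main scaling the pooled ratios at day 6 would be lower. The Th2 list had a median of -0.20 (0.17 with zeros at their floor, 0.31 when scaled by fragments on genes) and a pooled ratio of 2.07 (1.44 to 2.93), which was 1.54 (1.01 to 2.29) without Ecm1. The Treg list had a median of -0.92 and a pooled ratio of 1.10 (0.637 to 1.82), and glycolysis genes -0.27 (0.23 when scaled by fragments) and 1.16 (0.882 to 1.5). The naive and quiescence list was higher in both (0.37, and 2.17 with an interval of 1.22 to 3.69), though 1.68 (0.853 to 3.10) without Igfbp4. T cell markers had a median of -1.93 (percentile 1.09, or -0.04 with zeros at their floor) on 6 fragments in NLRP3KO against 51 in WT, a pooled ratio of 0.662 (0.232 to 1.54). The non-polyadenylated list had a median of -1.53.

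Of 5336 genes kept at day 6, 1113 were at least 2-fold higher and 2869 lower in NLRP3KO, with 59.2% listed at 0 in 1 library. Random splits gave on average 1462 higher and 2344 lower (at most 1547 and 2418), where observed fragments gave 1075 and 2817. With values above 0 in both and bounds apart, 9 genes were higher and 31 lower by at least 2-fold. The median log2 difference of genes above 0 in both was 0.33, and 0.83 when scaled by fragments on genes. The genes used for scaling were those with an FPKM of at least 1 in all libraries, this shallow one included.

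The genotype differences at the 2 times were compared across genes, which are not independent replicates; these comparisons shared no library. Over 7178 genes Pearson's correlation was 0.087 and Spearman's 0.112, and over the 176 genes with at least 40 fragments over the 4 libraries, at least 10 of them at day 6, they were 0.518 and 0.466. The 50 genes that were higher in NLRP3KO at day 3 with bounds apart, pooled, were 3.19 times (2.87 to 3.55) WT at day 3 and 2.52 times (2.15 to 2.94) WT at day 6, from 235 and 526 fragments. Without Malat1 the day 6 ratio was 2.38 (2.00 to 2.84), and 41 of the 50 genes lay in the same direction. In 1000 sets of other genes matched on day 3 fragments, the day 6 ratio had a median of 0.945 (0.770 to 1.18) and a maximum of 1.62, and 22.4 genes on average (at most 32) were higher at day 6. The lower set, 34 genes with fragment numbers, gave 0.651 (0.612 to 0.693) at day 3 and 0.901 (0.814 to 0.996) at day 6. Lars2, a mitochondrial leucyl-tRNA synthetase gene, held most of its fragments. Without this gene the ratio was 0.302 (0.253 to 0.358) at day 3 and 0.424 (0.303 to 0.578) at day 6, from 43 and 571 fragments, against a median of 0.956 (0.732 to 1.28) and a minimum of 0.623 in 1000 random sets. Of these 33 genes, 32 were lower at day 6, against 18.2 on average (at most 30) in the random sets, in which zeros of the shallow library also counted as lower. The matched sets and the values without Malat1 or Lars2 were chosen after seeing the data.

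**Figure D2:**
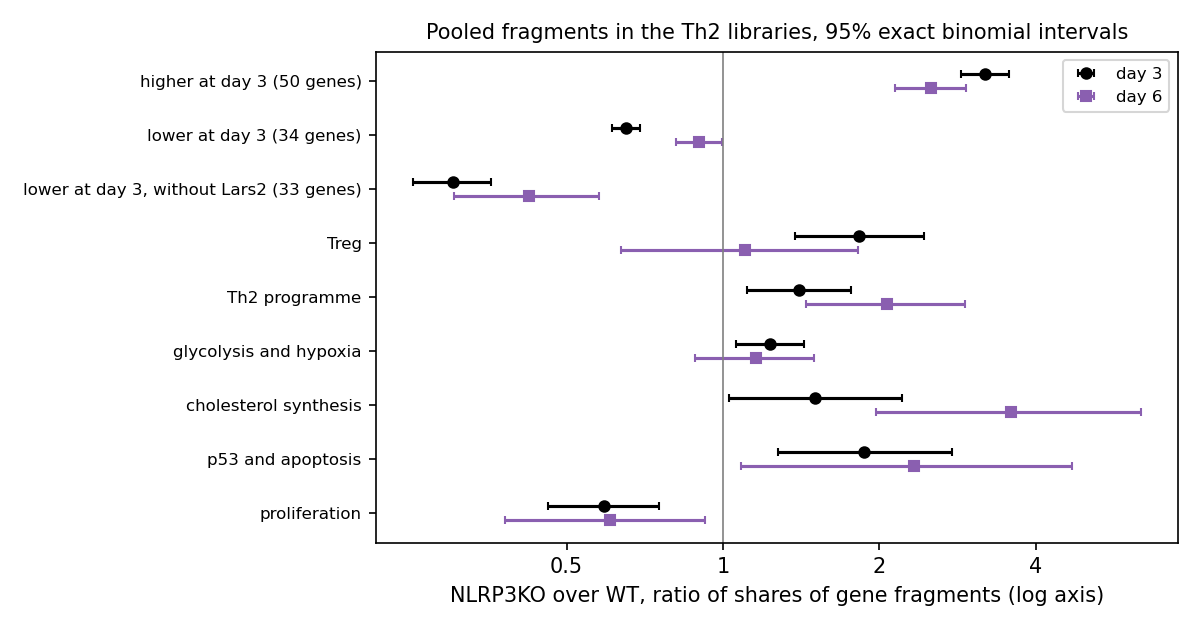
Ratio of NLRP3KO to WT of pooled fragments as a share of gene fragments (log axis), at day 3 (circles) and day 6 (squares), with exact 95% binomial intervals that cover counting error. The 50 genes higher at day 3 stand at 3.19 and 2.52, and the lower genes without Lars2 at 0.302 and 0.424.

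Between day 3 and day 6 of WT culture, Cish, an inhibitor of cytokine signalling induced through STAT5, was higher at day 6, at 19.4 against 5.75 (log2 difference 1.53). Atf4 was also higher, at 29.2 against 10.5 (1.29), as was Lsm4, an RNA-binding protein gene, at 22.2 against 2.08 (3.00). Lower at day 6 were the adaptor gene Dok2 at 1.13 against 10.5 (-2.86), Cyba, a subunit of the phagocyte oxidase, at 2.87 against 18.9 (-2.65), the kinase gene Pim2 at 2.81 against 13.1 (-2.16), and Hspa5, the chief chaperone of the endoplasmic reticulum, at 5.94 against 18.8 (-1.71). The Th2 list differed little (median -0.12, percentile 21.0, pooled ratio 0.841, 0.656 to 1.08), and proliferation genes had a pooled ratio of 1.06 (0.872 to 1.29). Cholesterol synthesis genes were lower at day 6, with 4 of 11 at least 2-fold lower, a median of -0.85 (percentile 0.55) and a pooled ratio of 0.618 (0.386 to 0.976). With a minimum FPKM of 5 that median was 0.34. Tfh genes had 3 of 5 higher (median 1.30, percentile 97.7, 0.98 with zeros at their floor) and a pooled ratio of 1.91 (0.853 to 4.57), on 20 and 10 fragments.

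In NLRP3KO cells S100a13 was higher at day 6, at 67.9 against 7.39 (2.98). Lower at day 6 were Canx, a lectin chaperone gene, at 1.88 against 15.0, Cd4 at 2.62 against 12.8, the costimulatory receptor gene Cd28 at 1.85 against 9.58, these 3 on an estimated 0.6 to 0.8 fragments at day 6, and Hsp90ab1 at 18.0 against 71.0 (-2.08). The Treg list had 5 of 8 members lower and 1 higher (median -1.21, percentile 1.22, -0.44 with zeros at their floor), with Tnfrsf18 listed at 0 at day 6 and 29.3 at day 3. Its pooled ratio was 0.682 (0.398 to 1.11). Over all 5207 genes kept, 2695 were at least 2-fold lower and 1091 higher, so the count of lower members alone says little here too. T cell markers had a median of -2.18 (percentile 0.30, -0.36 with zeros at their floor) and a pooled ratio of 0.567 (0.198 to 1.32).

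In WT, 1346 of 5592 genes were at least 2-fold higher and 1129 lower at day 6, and in NLRP3KO 1091 of 5207 were higher and 2695 lower. By fragments, genes above 0 in both and with bounds apart numbered 25 in WT against 13.3 on average in the splits (6 to 22). In NLRP3KO they numbered 5 against 6.52 (1 to 13), so a difference with time in NLRP3KO was not detectable by this count at this depth. Median differences in NLRP3KO were 0.42, or 0.79 when scaled by fragments on genes. Time was also confounded with sex markers. Xist (chromosome X, 100655712 to 100678572), the noncoding RNA of the inactive X chromosome, had FPKM of 13.7 in WT day 3 and 17.6 in NLRP3KO day 3 and was listed at 0 in both day 6 libraries. The Y-linked genes Ddx3y, Kdm5d and Uty were 0.395, 1.00 and 0.699 in WT day 6, and Eif2s3y was 14.3 in NLRP3KO day 6. All 4 were listed at 0 in the naive and day 3 libraries, where Xist was 27.1 in naive WT and 37.8 in naive NLRP3KO.

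**Figure D3:**
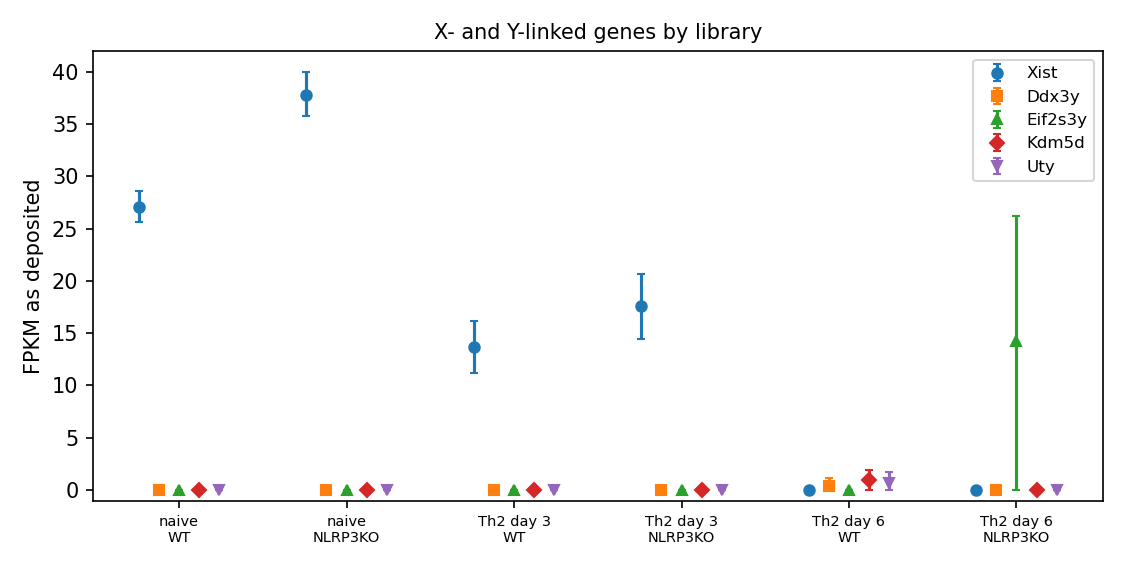
FPKM of Xist and of 4 Y-linked genes in each of the 6 libraries. Xist is above 0 in the 4 naive and day 3 libraries and at 0 at day 6, where Y-linked genes are above 0.

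Naive cells of both genotypes were compared to show how the libraries of the genotypes differed without Th2 culture. Ribosomal protein genes were lower in naive NLRP3KO. Of 20 genes, 18 were lower and 1 higher with bounds apart and 5 were at least 2-fold lower, with a median of -0.75 (percentile 0.45) and a pooled ratio of 0.681 (0.668 to 0.694). Removing the length trend among genes with an FPKM of at least 60, chosen after seeing the data, left -0.26 (bootstrap interval -0.53 to -0.08). Rpl34 was 35.1 against 219 (log2 difference -2.92), Rpl35 301 against 811 (-1.84) and Rpl10a 225 against 446 (-1.39). Dapl1, a gene of resting T cells, was 82.4 against 293 (-2.20), Ndufs6, of respiratory complex I, 7.88 against 37.1 (-2.17), and Tomm7, of the mitochondrial import complex, 17.6 against 53 (-1.79). Higher in NLRP3KO were Tcn2, a vitamin B12 carrier gene, at 13.9 against 2.83 (1.19), Cd2bp2 at 18.6 against 4.79 (1.11) and the class I genes H2-T22 at 39.8 against 12.4 (1.08) and H2-Q6 at 155 against 41.8 (1.41). Rps27 and Hnrnpa1 were listed at 0 in naive WT and were 55.1 and 7.38 in NLRP3KO, so a 0 of such widely expressed genes can be a failed estimate.

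Cholesterol synthesis genes were slightly higher in naive NLRP3KO (14 entries, median 0.25, percentile 99.8, pooled ratio 1.38, 1.26 to 1.52), as were interferon-stimulated genes (17, 0.24, 99.7 and 1.29, 1.21 to 1.38) and Treg genes (14, 0.22, 99.3 and 1.22, 1.13 to 1.31). No member of these 3 lists was 2-fold apart, and their medians stayed positive under each scaling. The random lists were not matched on transcript length, with which differences between these libraries varied. With the length trend of all genes removed, a test chosen after seeing the data, the medians were 0.20 (bootstrap interval -0.03 to 0.35) for cholesterol synthesis, 0.17 (0.02 to 0.43) for interferon-stimulated and 0.14 (0.01 to 0.32) for Treg genes. Without that removal the intervals were 0.11 to 0.43, -0.07 to 0.37 and -0.09 to 0.33, in the same order. Those of interferon-stimulated and Treg genes thus reached below 0 before the removal, and that of cholesterol synthesis genes after it. The Th2 list had a median of 0.08 (percentile 74.0). Markers of other cells differed between the same libraries. B cell markers were lower in NLRP3KO, with 6 of 7 lower and bounds apart, a median of -0.72 (percentile 0.00) and a pooled ratio of 0.394 (0.325 to 0.476). Markers of dendritic cells and antigen presentation, of which 3 of 6 were kept, had a pooled ratio of 0.412 (0.357 to 0.474). T cell markers had 1.07 (1.03 to 1.11), with 4 higher and 3 lower with bounds apart. Erythroid markers had a pooled ratio of 0.396 (0.360 to 0.436), but their 8 entries went both ways, with 4 lower and 2 higher with bounds apart and a median of -0.45 (percentile 7.29). The granzyme gene Gzma was 1.38 against 8.41, and the non-polyadenylated list had a median of -0.63.

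Of 9985 genes kept, 21 were at least 2-fold higher and 232 lower in naive NLRP3KO. With FPKM as deposited, where the median of genes above 0 in both was 0.37 in place of 0.01, the split was 474 higher and 195 lower. Under that scaling the medians of the naive and quiescence list (-0.08), glycolysis (-0.09) and p53 genes (-0.04) turned positive, while that of ribosomal protein genes stayed negative (-0.33). Random splits of the fragments gave 1.73 higher and 1.84 lower on average, so these naive libraries differed beyond counting error.

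Th2 day 3 cells were compared with naive cells of the same genotype, a comparison confounded with RNA selection, since naive libraries came from purified mRNA and Th2 libraries from RNA depleted of ribosomal RNA. In WT, Irf4 was 21.9 against 2.33 (log2 difference 4.68), Cdkn1a, an inhibitor of cyclin-dependent kinases, 11.3 against 0.252 (4.45), Il2ra, the IL-2 receptor alpha chain gene, 24.0 against 5.97 (4.06), and the glycolytic enzyme gene Tpi1 42.1 against 17.7 (3.66). Nfil3, a transcription factor induced by IL-4, was 7.17 against 0.723 (3.64). In NLRP3KO the highest included Cdkn1a at 26.2 against 0.186 (5.51), Tgm2 at 17.3 against 0.191 (4.92), Egln3 at 20 against 1.42 (4.76), Ecm1 at 58.8 against 15.7 (4.44) and the cytokine gene Lif at 11.5 against 0.266 (4.33). Lower than in naive cells was Tcf7, a transcription factor of naive T cells, at 2.39 against 182 (-3.38) in WT and 2.02 against 363 (-4.29) in NLRP3KO. S1pr1, needed for exit from lymph nodes, was 1.72 against 95.8 (-2.86) in WT and 0.730 against 135 (-3.89) in NLRP3KO. Dapl1 was listed at 0 in both day 3 libraries.

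The Th2 list was higher at day 3 in both genotypes, with 10 of 11 members at least 2-fold higher in WT (median 2.33) and 11 of 13 in NLRP3KO (2.44), and pooled ratios of 9.17 (7.62 to 11.0) and 11.1 (9.38 to 13.1). It stayed positive as deposited (0.20 and 0.60). Glycolysis genes had pooled ratios of 5.59 (4.98 to 6.25) in WT and 6.65 (5.95 to 7.42) in NLRP3KO, and proliferation genes 7.48 (6.42 to 8.67) and 3.74 (3.03 to 4.57). For p53 genes they were 3.83 (2.77 to 5.16) and 7.41 (5.73 to 9.46), and for cholesterol synthesis 3.21 (2.37 to 4.26) and 3.49 (2.68 to 4.48). The medians of these last 4 lists turned negative with FPKM as deposited. Naive and quiescence genes were lower, 10 of 13 at least 2-fold in each genotype (medians -2.29 and -2.24), as were interferon-stimulated genes (-1.28 and -1.99, or -1.11 and -0.04 with zeros at their floor), ribosomal protein genes (-1.52 and -0.81) and T cell markers (-1.67 and -1.75). Non-polyadenylated RNAs, which mRNA purification removes, had medians of 5.04 and 4.40. Erythroid markers had medians of -4.45 in WT and -3.68 in NLRP3KO, all 8 entries listed at 0 at day 3, and -1.63 and -0.33 over the 3 and 2 entries that could be placed at their floor. B cell markers had medians of -1.27 and -0.98, with 6 of 7 (WT) and 7 of 7 (NLRP3KO) listed at 0 at day 3.

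Of 9562 genes kept in WT, 955 were at least 2-fold higher and 2994 lower at day 3, and of 10048 in NLRP3KO, 1089 were higher and 3222 lower. As deposited, with median differences of -1.91 and -2.16, the splits were 221 and 8253 in WT and 264 and 8878 in NLRP3KO. Genes above 0 in both libraries and apart by fragments numbered 879 in WT and 804 in NLRP3KO, against averages of 110 and 105 in random splits.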

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

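Among the named genes, Srgn alone was at least 2-fold apart, with bounds apart, in opposite directions in 2 groups, and no test was run on it before or after this was seen. Its log2 difference between day 3 and naive cells was -2.01 in WT and 1.38 in NLRP3KO, so the single WT pair lay one way and the single NLRP3KO pair the other. Srgn, the core protein of a granule proteoglycan, had FPKM of 164 in naive WT and 161 in naive NLRP3KO, 6.27 and 58.4 at day 3, and 29.0 and 19.5 at day 6, in the same order of genotypes. Without scaling, both day 3 values lay below the naive ones, so the sign of the NLRP3KO difference depended on scaling. That change is not among the 7 sign changes of named genes counted below. The difference between the genotypes in this respect was not tested, since each group had 1 library.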

How the results depend on the processing

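The count of genes above 0 in both libraries with bounds apart, scaling over 5 libraries and scaling by fragments on genes were chosen after the data had been seen; the other settings were set before. Of 135 recomputed counts and correlations, 90 stayed within 1.5 times the main value or its interval and 45 did not. Of 721 list medians, 10 that had lain outside the central 95% of random lists changed sign; of the others, 582 moved by less than 1 SD of matched random lists and 129 by more, some of them across 0. Of 3418 values of named genes, 7 with bounds apart changed sign; of the others, 2935 moved by less than the width of their bounds and 476 by more. With a pseudocount of 0.1 the naive genotype comparison gave 265 genes higher and 536 lower, and 4617 (WT) and 5224 (NLRP3KO) genes were lower at day 3 than in naive cells, since a smaller pseudocount shrinks low genes less. A minimum FPKM of 5 kept fewer genes. It gave 302 higher and 286 lower in NLRP3KO at day 3, 398 and 555 at day 6, 257 and 146 between the days in WT, 391 and 432 between them in NLRP3KO, and 388 (WT) and 504 (NLRP3KO) higher at day 3 than in naive cells. It left 20 of 98 list medians outside the central 95% of random lists, against 32 of 109, and the median of cholesterol synthesis between the days in WT became 0.34. With no minimum, 1733 genes were lower at day 6 in WT, and Spearman's correlation of the day 3 and day 6 genotype differences was 0.0696. With FPKM as deposited, which shift the median of all genes, 474 genes were higher in naive NLRP3KO. Day 3 against naive cells then gave 221 higher and 8253 lower in WT and 264 and 8878 in NLRP3KO. That shift also turned medians of this comparison negative. Among lists outside the central 95% of random lists, these were in WT proliferation (-0.027), glycolysis (-0.14), cholesterol synthesis (-0.83) and p53 genes (-1.32), with Tnfrsf4 at -0.25. T cell activation (-1.86) and stress response genes (-2.16), which lay inside that range, turned negative too. In NLRP3KO, among such lists, they were Treg (-1.65), proliferation (-1.15), glycolysis (-0.13), cholesterol synthesis (-0.97) and p53 genes (-1.22), with Gata3 at -0.16, Tnfrsf18 at -0.44, Ctla4 at -0.80, Tfrc at -0.34, Top2a at -0.19 and Cyp51 at -0.30. Counting only genes with bounds apart gave 108 higher and 145 lower in NLRP3KO at day 3, 11 and 658 at day 6, 74 and 79 between the days in WT, 3 and 435 in NLRP3KO, and 285 (WT) and 269 (NLRP3KO) higher at day 3 than in naive cells. When values also had to lie above 0 in both, 7 genes were higher in naive NLRP3KO, 47 higher and 32 lower at day 3, and 9 and 31 at day 6. Between the days there were 9 and 17 in WT and 3 and 13 in NLRP3KO, and against naive cells 280 and 552 in WT and 257 and 513 in NLRP3KO. These rules count fewer genes by construction; for other moves the cause was not tested. Depth limited the Th2 comparisons, among them those with NLRP3KO day 6 and its 4358 fragments on genes. No paired analysis was possible within a comparison, because each sets 1 library against 1. Pairing the genotypes by stage over all 6 libraries was possible but was not run.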

Other observations

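Across the 3 stages, pooled cholesterol synthesis genes were higher in NLRP3KO each time, at 1.38 times WT in naive cells, 1.5 times at day 3 and 3.58 times at day 6. Their median differences were positive under each scaling, while the interval of the naive median reached below 0 once the length trend was removed (-0.03 to 0.35) and the day 3 interval reached 1 without Hmgcs1 (0.906 to 2.02). Proliferation genes were pooled at 1.18 times WT in naive cells (median 0.08, percentile 84.8), 0.589 at day 3 and 0.606 at day 6. For p53 and apoptosis genes the ratios were 0.965 (0.860 to 1.08) in naive cells, 1.87 at day 3 and 2.33 (1.08 to 4.71) at day 6, the last on 12 and 29 fragments, with 4 members at least 2-fold higher, 4 lower and 7 of 11 listed at 0 in 1 library. Inflammasome genes stood at 1.12 (1.04 to 1.20) in naive cells, with a median of 0.04 (percentile 52.9). At day 3 they stood at 2.11 (0.965 to 4.88), and leaving out single members moved this between 1.16 and 3.95. At day 6 they stood at 2.05 (0.475 to 6.91), on 4 and 11 fragments and with a median of -0.63 in the other direction.

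Of the other lists, Th1 genes had pooled ratios of 0.877 (0.795 to 0.966) in naive cells, 1.06 (0.547 to 2.03) at day 3 and 0.938 (0.177 to 3.21) at day 6. Their naive median of 0.10 (percentile 83.5) lay the other way, but was -0.08 with zeros at their floor. T cell activation genes had 1.11 (1.04 to 1.19), 0.952 (0.663 to 1.36) and 0.924 (0.440 to 1.76), with a naive median of 0.05 (percentile 72.2). Tfh genes had 1.09 (0.987 to 1.21), 1.97 (0.854 to 4.83) and 0.563 (0.0638 to 2.32), and stress response genes 0.954 (0.892 to 1.02) in naive cells and 0.792 (0.346 to 1.60) at day 6. Naive and quiescence genes had a median of -0.31 at day 3 (percentile 18.3), a pooled ratio of 1.06 (0.732 to 1.52) and 0 members 2-fold apart. Th17 genes (2 kept, median 0.20), cytotoxic granule genes (5 kept, 0.15, but -0.09 over 4 with zeros at their floor), CD8 T cell (2 kept, -0.14), mast cell (1 kept, 0.09), NK cell (1 kept, -0.65) and monocyte and neutrophil markers (5 kept, -0.06, and 0.27 as deposited) were measured in naive cells, where each kept under 6 genes. At day 3 the Th17, CD8, NK, monocyte, mast cell and erythroid lists had 0 genes kept. Interferon-stimulated genes at day 6 of WT culture were 3.82 times (1.03 to 21.1) day 3, on 12 and 3 fragments.

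Of the tests that follow, those on Xist, the length test of ribosomal protein genes and the day 6 test of day 3 genes were chosen after the result was seen, as were the matched random sets and the size of the length trend at day 3.

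Ribosomal protein genes were lower in naive NLRP3KO (median -0.75, bootstrap interval -0.85 to -0.46). Counting error did not account for this, as the lowest median in 100 random splits was -0.046, nor did GC content, after whose removal the median was -0.81 (-1.0 to -0.51), and -0.60 (-0.91 to -0.36) against abundant genes alone. Transcript length remained open. Removing the trend of all genes left -0.54 (-0.68 to -0.33), and after short abundant genes had been seen to be lower too, removing the trend among genes with an FPKM of at least 60 left -0.26 (-0.53 to -0.08). The 91 other abundant genes under 700 bases had a median of -0.61 and the 192 of at least 1600 bases 0.13. The trend with transcript length may thus account for much of the difference, while genotype stays confounded with library. What gave rise to that trend was not tested.

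Xist was listed at 0 in both day 6 libraries. Low depth was argued against by the 20.5 fragments expected in NLRP3KO day 6 at the day 3 level and 98.6 in WT day 6. In these libraries 4 values lay above 0 on the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y, 3 in WT and 1 in NLRP3KO, each with a lower bound of 0. They are consistent with day 6 cells from male and day 3 and naive cells from female mice, which would confound time with sex and mouse. So near the floor they do not exclude loss of Xist in female cells with time, which stays open. The labels used here name no sex.

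The genotype difference at day 3 exceeded counting error, with 79 genes apart by fragments, at any size of difference, against at most 20 in 100 random splits. The trend with transcript length was too small to account for the genes 2-fold apart by their deposited bounds. Its removal left 98.7% of them 2-fold apart (75 of 76, with 3 more lacking a transcript). Since these genes differed by at least 1.03, most had to stay, so that share itself decides little. The trend had medians from -0.25 to 0.14, and its removal moved none of 1094 genes by more than 0.303. It took 27 of them below a 2-fold difference and brought 25 above it, while the genes apart differed by a median of 1.95. The genes higher at day 3 were 2.52 times WT at day 6, above all 1000 matched random sets (at most 1.62), in libraries whose sex markers differed from those at day 3. This is consistent with a difference that goes with genotype. Whether lack of NLRP3, differences between the mice or the cultures used or genes carried along with the targeted locus account for it was not tested.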
